A study of Caenorhabditis elegans with 2 samples.

How the data were processed

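Total RNA of whole C. elegans was labelled with Cy3 after amplification to cRNA, per the labels' protocols, and hybridised to 2 arrays of the same C. elegans design, 1 for worms on OP50 and 1 for worms on B. licheniformis 141. Groups were taken from the sample titles and source names, each with 1 biological replicate. No label gives the culture temperature or how many worms were pooled. The treatment text names B. licheniformis 141 on both samples, so the title and source name decided the group of the control.

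Scanner intensity values were made by the authors with Agilent Feature Extraction 11.0.1.1 for the OP50 array and 11.5.1.1 for the B. licheniformis 141 array, per the file headers. The processed signal is a spot's brightness after subtraction of background within the array, with no scaling between arrays, and the median spot and background signals are unprocessed. The detector setting was 460 for OP50 and 435 for B. licheniformis 141. No spot was saturated, and the spike-in spots lay at background (median 6.09 and 4.11 units), so they could not serve for scaling. The median coefficient of variation of replicate probes was 5.58% on the OP50 array and 8.98% on the B. licheniformis 141 array, the latter outside the range the software accepts. The deposited series table holds log2 values without a stated scale. They equalled log2 of the processed signal within 0.001 for 99.97% and 99.98% of probes, with medians of 8.00 and 7.89, so they are uncentred and of known direction.

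Each array held 45220 spots, of which 1417 control spots were left out. The other spots formed 43603 probes, 50 of them with 5 spots, and spots of a probe were averaged. The 75th percentile of the processed signal was 3298 units on OP50 and 2580 on B. licheniformis 141, and the main value is log2 of the processed signal minus that percentile. Spots marked as non-uniform or population outliers were dropped (6 and 7 spots). A probe entered where it was well above background on both arrays, and a gene is the mean of its probes that entered. Names came from the files. Of the probes, 34320 matched a RefSeq gene table of assembly WBcel235, 30978 by sequence name and 3342 by accession. A further 1077 kept a sequence name that the table lacks, and 8206 had no gene name. The arrays were designed on an older genome build, so that table served for names, overlaps and gene spans only and no coordinates are given. In all 20439 genes had a probe, 19814 of which are in the table.

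A gene was counted as changed at 2-fold or more. A gene with every probe not well above background on 1 array has only a bound, the bright array's value against the higher of the dim probe's own value and the lowest signal that counted as well above background there (24.7 units on OP50, 12.77 on B. licheniformis 141). Genes well above background on neither array (3290) and genes measured on each array by different probes (16) have no value. With 1 array per diet there were no degrees of freedom left for a test, so the number of arrays limits the precision. The technical spread came from 26 probes with 5 spots well above background (SD 0.12 on OP50 and 0.16 on B. licheniformis 141) and from 4429 genes with several probes. Where such a gene differed at least 2-fold, its probes had 1 direction in 98.6% of 1093 genes, a share raised by choosing genes for a large mean difference, and over all 4429 genes in 76.1%.

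A set of 43 gene lists covering serotonin, insulin-like and stress signalling, detoxification, immunity, metabolism, tissues, germline and large gene families was fixed before the data were examined. Each list's median difference was ranked among 10000 random lists of the same size, matched on mean signal in 20 bins, and a list stood apart in the lowest or highest 2.5%. Lists needed at least 3 measured genes. The rule for named genes was fixed at the same time. It took the 15 highest and 15 lowest genes whose probes had the same direction, every serotonin gene, the 2 highest and 2 lowest members of each other list described, and the 5 highest bounds in each direction among genes measured on 1 array. Other members of the propionate shunt, methionine cycle and insulin-like signalling lists, and fem-1, were named after their values were seen.

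The steps were tested on simulated data made from the 15286 genes. For single genes the noise had the size seen between probes (SD 0.39). Of 100 genes changed by 1.5 on the log2 scale, 83.0% were recovered at the 2-fold threshold, as were 100.0% of 100 genes changed by 3, and 1.12% of unchanged genes passed it. That noise is technical spread within these arrays and holds no variation between worm pools, slides or scans, so these shares are no rate of false calls between separate samples. For lists the noise had the spread of the observed differences over genes (SD 1.15), drawn separately for each gene, so genes that move together were not simulated. Of 100 lists of 20 unshifted genes 4.0% stood apart, as did 90.0% of 20 lists shifted by 1.

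Alternatives fixed beforehand were normexp background correction with an offset of 50, no background correction, quantile, median and loess normalisation, a percentile over detected probes, no filter and a stricter filter on dim probes, the brightest probe of a gene, the authors' deposited log2 values, outlier spots kept, thresholds of 1.5-fold and 3-fold, list means, unmatched random lists and another detection flag. The mean spot signal planned for the background corrections is not a column used here, so the median spot signal took its place. Alternatives added after seeing the data were a normexp correction with 3 faulty local backgrounds replaced, no scaling between arrays, removal of a trend on gene span, and random lists matched on span in 5 bins and signal in 10. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and R 4.3.3 with limma 3.58.1.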

Results

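Whole-animal RNA of Caenorhabditis elegans strain CF512 was measured on 2 Agilent 1-colour oligonucleotide arrays, 1 for each diet. CF512 carries the mutations fer-15(b26) and fem-1(hc17), and fertility genes of this kind are used to obtain worms that do not reproduce. Both alleles are temperature-sensitive, and no culture temperature is stated in the sources used here, so whether these worms were sterile is not known. Worms were raised on Escherichia coli OP50, the standard laboratory food, to the last larval stage or young adulthood, and RNA was taken after 24 h on a lawn of 20 mg of bacteria. The control lawn was OP50 and the other lawn was Bacillus licheniformis 141. The title of the series ties this isolate from Korean fermented food to longer life through serotonin signalling, so the comparison asks which worm transcripts, those of serotonin signalling included, differed with the food. Differences are B. licheniformis 141 minus OP50 on the log2 scale. With 1 array per diet no difference has a replicate check and no p-value is given.

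Of 43603 probes, 31503 (72.2%) were well above background on the OP50 array and 34171 (78.4%) on the B. licheniformis 141 array, and 15286 genes were measured on both. At least 2-fold higher on B. licheniformis 141 were 2894 genes (18.9%), and at least 2-fold lower were 1412 (9.24%), so that 67.2% of the changed genes were higher. At least 8-fold differences numbered 366 higher and 54 lower, and at least 64-fold differences 29 higher and 5 lower. Technical spread was smaller than the 2-fold threshold of 1 on the log2 scale. Replicate spots gave an SD of 0.20 for a difference, and different probes of a gene a root mean square SD of 0.39. The split depended on the scaling. Centring each array on its median moved the median difference of all genes from 0.07 to -0.18 and gave 2167 genes higher and 2379 lower (47.7% higher), and leaving the arrays unscaled gave a median of -0.29 with 1877 higher and 2893 lower (39.4% higher). A planned background correction by normexp, which 3 spots with faulty local background distorted, moved the median to 0.72. The arrays lay on different slides and were scanned 594 days apart with different software versions and detector settings, so slide, scan and diet cannot be told apart.

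The glutathione S-transferase genes gst-21 (ZK697.6) and gst-35 (Y1H11.2) led the genes with the highest differences, with 562-fold and 517-fold higher signal, differences of 9.13 and 9.01. The nematode-specific peptide gene nspg-7.2 was 449-fold higher, the lysozyme gene lys-10 was 213-fold higher and the infection response gene irg-5 was 183-fold higher. The homeobox gene tab-1 was 130-fold higher with both of its probes within 0.01 of each other (7.02). The methyltransferase family gene comt-4 was 124-fold higher, although its 2 probes gave 6.02 and 7.90. The lectin domain gene clec-174 was 105-fold higher and cld-1 112-fold higher. The remaining 6 of the 15 highest genes were F49E12.10 (209-fold), Y65B4BR.1 (198-fold), W03F9.4 (169-fold), F49F1.5 (114.2-fold), C15B12.8 (106-fold) and C05G5.5 (105-fold). The annotated spans of comt-4 and C05G5.5 overlap other genes.

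The lowest difference belonged to acdh-1 (C55B7.4), the acyl-CoA dehydrogenase that opens the propionate shunt. Its processed signal was 76407 units on OP50 and 20.8 on B. licheniformis 141, a difference of -11.49 or 2876-fold, and both of its probes lay between -11.70 and -11.28. The size of the difference depended on the background correction, with -6.85 under planned normexp, -9.59 under normexp with 3 faulty backgrounds replaced and -9.67 without correction. The lower value was close to the 12.77 units at which probes of that array began to count as well above background. F18E3.12 was 260-fold lower, T05E12.6 82.3-fold lower with 3 probes, T13F3.6 71.7-fold lower and the chemoreceptor family gene srh-237 65.7-fold lower. The glucuronosyltransferase genes ugt-32 and ugt-66 were 55.4-fold and 27.1-fold lower (-1.84 and -0.86 under planned normexp, -4.26 and -3.26 with its faulty backgrounds replaced), the lectin domain gene clec-47 52.4-fold lower and the acyltransferase family gene oac-32 44.8-fold lower. The folate transporter family gene folt-2 was 40.2-fold lower across 5 probes, from -5.64 to -4.80. The short-chain dehydrogenase gene dhs-26 was 30.7-fold lower and acs-1, an acyl-CoA synthetase gene, 24.8-fold lower. C30G12.2 (51.9-fold), F18E3.11 (28.3-fold) and T22B7.7 (22.5-fold) completed the 15 lowest genes. T13F3.6, dhs-26 and acs-1 overlap other annotated genes.

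The folds of these 30 genes depended on the background correction. Under planned normexp 26 of the 30 moved by over 1.5 times, 19 did so with the faulty backgrounds replaced and 17 without correction, each to a smaller difference. With the faulty backgrounds replaced nspg-7.2 gave 7.67, lys-10 6.31 and clec-174 5.09. F18E3.12 gave -6.81 (-4.47 under planned normexp), T05E12.6 -5.05 (-2.98), C30G12.2 -4.55 (-2.18), oac-32 -4.31 (-2.14) and srh-237 -4.11 (-1.53). All 30 stayed at least 2-fold in the same direction under the 3 corrections, except ugt-66 under planned normexp. Of 215 genes followed through the settings, 28 changed sign under planned normexp and 0 with its 3 faulty backgrounds replaced. Leaving the arrays unscaled lowered every difference by 0.35, which turned 11 small positive differences negative.

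**Figure D1:**
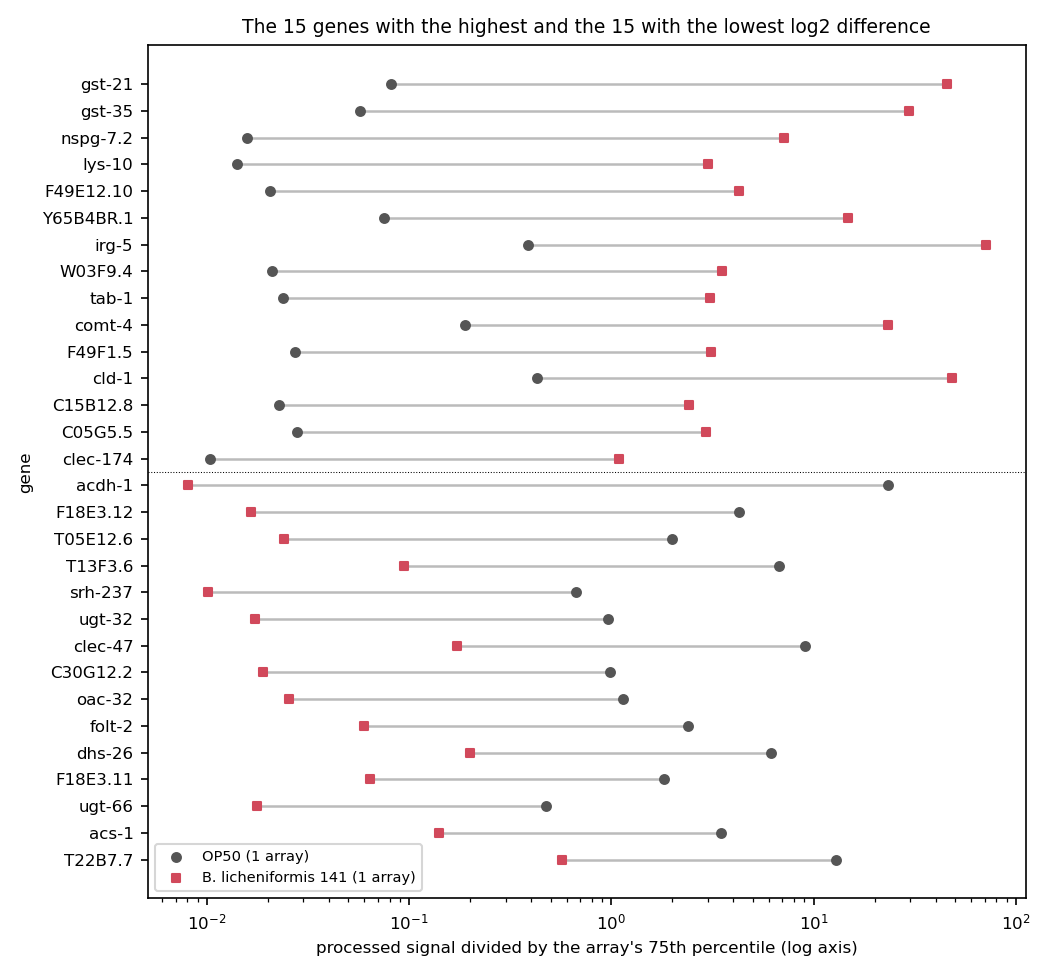
Processed signal divided by the array's 75th percentile (log axis) of the 15 genes with the highest and the 15 genes with the lowest difference, with OP50 as grey circles and B. licheniformis 141 as red squares, 1 array each. The span of each line is the difference, from 562-fold higher for gst-21 to 2876-fold lower for acdh-1.

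A further 1651 genes were well above background on the B. licheniformis 141 array only and 195 on the OP50 array only. For these the difference has a lower bound, taken against the higher of the gene's own signal on the other array and the dimmest signal that counted as well above background there. Among the 1651 genes 587 were at least 2-fold higher by this bound and 86 at least 8-fold. The highest bounds were C02E7.6 (at least 214-fold higher), the cuticle collagen gene col-146 (at least 141-fold, 6 probes), the cuticle collagen genes sqt-1 (at least 62.1-fold) and col-88 (at least 60.2-fold), and Y73B6BL.37 (at least 50-fold). Among the 195 genes 160 were at least 2-fold lower and 17 at least 8-fold. They were led by nspe-7 (at least 44.7-fold lower) and by acdh-2 (at least 43.8-fold lower, 5 probes), an acyl-CoA dehydrogenase gene like acdh-1. W03G1.4 (at least 23.3-fold), Y38H6C.21 (at least 21.6-fold) and K02B7.1 (at least 19.7-fold) followed. The unequal numbers of 1651 and 195 genes go with the lower detection limit of the B. licheniformis 141 array, 12.77 against 24.7 units before scaling. Whether that limit accounts for the unequal numbers past 2-fold and 8-fold was not tested.

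Serotonin genes did not stand apart from other genes. Of 15 genes for serotonin synthesis, transport, receptors and breakdown, 11 were measured on both arrays, with a median difference of -0.22 at percentile 16.3 of 10000 random lists of the same size and signal. Only bas-1, the decarboxylase that makes serotonin and dopamine, was at least 2-fold lower (-1.04, 3 probes from -1.20 to -0.95), and only cat-4 at least 2-fold higher (1.77). The product of cat-4 makes the cofactor of the hydroxylase that starts serotonin synthesis. Its value came from 1 of 6 probes, since the other 5 were not well above background on both arrays, and it turned to -0.55 when all probes were used. The gene of that hydroxylase, tph-1, was not well above background on either array, nor were the receptor gene ser-1 and the channel gene lgc-50. The transporter gene cat-1 was above background on OP50 only. Receptor genes gave 0.72 for ser-4, -0.85 for ser-5, -0.52 for ser-7 and -0.55 for the channel mod-1. The reuptake transporter gene mod-5 gave 0.23, the amine oxidase genes amx-1 and amx-2 gave 0.34 and -0.84, and the cofactor genes ptps-1 and qdpr-1 gave 0.19 and -0.22. Under planned normexp ser-5, ser-7, mod-1 and amx-2 turned to 1.70, 0.97, 1.66 and 0.46, ser-4 and mod-5 rose to 1.73 and 2.71, and the list's median was 0.97, still within the random range. With the faulty backgrounds replaced all of these genes kept the sign of the main setting. Unscaled, mod-5, amx-1 and ptps-1 turned to -0.13, -0.01 and -0.16. The difference of bas-1 was short of 2-fold in 6 other settings, between -0.98 and -0.65. Without the filter on dim probes the list's median lay at percentile 0.97.

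Insulin-like signalling genes were lower and DAF-16 target genes higher. Of 10 measured components of the pathway 7 had negative differences and 3 were at least 2-fold lower, namely the insulin receptor gene daf-2 (-1.78, 7 probes), the PI3-kinase gene age-1 (-1.29) and daf-16 itself (-1.20), the FOXO transcription factor that the pathway restrains. The highest components were akt-2 (0.40) and pdk-1 (0.31), and the list's median of -0.83 lay at percentile 0.22. With the span trend removed daf-2 gave -0.86, age-1 -0.92 and daf-16 -0.46, all short of 2-fold, and the list's median was -0.49. Planned normexp likewise left daf-2 at -0.70 and daf-16 at -0.73. DAF-16 class 1 targets, which the factor activates, had a median of 0.93 at percentile 99.99, with 8 of 20 genes at least 2-fold higher and 0 at least 2-fold lower. The desaturase gene fat-7 (86.4-fold) and the metallothionein gene mtl-1 (27.5-fold) led, and the lowest were aqp-1 (-0.43) and hsp-16.1 (-0.08). Class 2 targets, which are lower when DAF-16 is active, were higher as well, with a median of 0.60 at percentile 97.8. The highest were dod-24 (3.67) and dod-22 (2.92), and the lowest dod-17 (-1.77) and gcy-18 (-0.61). Under planned normexp dod-17 gave -0.46 and gcy-18 turned to 1.91. This list left the highest 2.5% under 6 of the other settings. Insulin-like peptide genes did not stand apart (median 0.11, percentile 27.7, 36 genes), with ins-2 at 4.69, ins-19 at 2.5, ins-6 at -1.69 (-0.18 under planned normexp) and ins-31 at -1.35. With the span trend removed that list's median was -0.26 at percentile 0.1, and under planned normexp it was 1.77.

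Glutathione S-transferase, cytochrome P450, SKN-1 target and antioxidant enzyme genes were higher as groups, and glucuronosyltransferase genes did not stand apart. Glutathione S-transferase genes had a median of 0.82 at percentile 99.99, with 19 of 44 genes at least 2-fold higher and 2 at least 2-fold lower. Besides gst-21 and gst-35 at the upper end, gsto-3 (-1.70) and gst-9 (-1.59) were the lowest, but turned to 0.50 and 0.05 under planned normexp. Cytochrome P450 genes had a median of 0.81 at percentile 99.98, with 30 of 62 genes at least 2-fold higher and 4 lower. They ranged from cyp-32B1 (90.2-fold higher) and cyp-13B1 (67.6-fold higher) to cyp-31A1 (-1.43, or 0.01 under planned normexp) and cyp-31A3 (-1.83). Planned normexp raised the P450 median to 2.01 and that of the glutathione S-transferases to 1.39. Targets of SKN-1, the factor of the oxidative stress response, had a median of 1.04 at percentile 99.95, with gst-5 (2.87) and gst-6 (2.57) highest and ugt-11 (-0.995, or 0.45 under planned normexp) and gcs-1 (-0.83) lowest. Most of these targets are also in the glutathione S-transferase or antioxidant list, so these lists are not separate results. The lowest members, ugt-11 and gcs-1, are in neither. Antioxidant enzyme genes had a median of 0.60 at percentile 99.7, with the catalase gene ctl-2 (1.67) and gpx-6 (1.49) highest and trxr-2 (-0.63) and gpx-4 (-0.56, or 1.99 under planned normexp) lowest. That list fell to percentile 94.1 when the mean replaced the median and to 92.2 with the span trend removed. Glucuronosyltransferase genes went both ways, with 17 of 61 at least 2-fold higher and 15 lower and a percentile of 75.6. Among them ugt-21 was 102-fold and ugt-18 80.7-fold higher.

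The PMK-1, irg and antimicrobial peptide lists of defence genes were higher, and lysozyme and C-type lectin domain genes did not stand apart. The PMK-1 list, a p38 MAP kinase pathway of intestinal immunity and its targets, had a median of 0.90 at percentile 99.89, with 7 of 15 genes at least 2-fold higher and 0 lower. Its highest members were irg-5 and irg-4 (96.9-fold higher), and its lowest were the transcription factor gene atf-7 (-0.82) and C17H12.8 (-0.10). The irg list, which shares irg-4 and irg-5, had a median of 0.67 at percentile 99.1 (94.5 with unmatched random lists), and its lowest members were irg-8 (-3.05) and irg-7 (-0.33, or 0.04 with the span trend removed). Antimicrobial peptide genes had a median of 0.78, at percentile 100, with 29 of 65 genes at least 2-fold higher and 4 lower. The saposin-like genes spp-12 (71.6-fold) and spp-18 (16.19-fold) led, and cnc-6 (-2.24) and fipr-18 (-1.18) were lowest, at -0.59 and -0.82 under planned normexp. Lysozyme genes lay at percentile 95.3 (median 0.50, 14 genes), or 98.4 without the filter on dim probes and 98.5 with the stricter one, with lys-10 and ilys-3 (1.86) highest and lys-6 (-3.77) and ilys-5 (-0.90) lowest, the last with probes that disagreed by an SD of 1.84 and a value of 0.40 from its brightest probe. C-type lectin domain genes lay at percentile 95.02 of the random lists, with 42 of 140 genes at least 2-fold higher and 23 lower. Other settings moved this list to either side, from percentile 2.15 under planned normexp to 99.85 with unmatched random lists. Among these clec-60 was 34.5-fold higher and clec-134 5.50-fold lower (-0.45 under planned normexp).

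Propionate shunt genes had the lowest median of the 43 lists in the main setting. This pathway breaks down propionyl-CoA where vitamin B12 is scarce. In the main setting all 7 measured genes had negative differences, 5 were at least 2-fold lower, and the median of -1.93 lay at percentile 0.0. After acdh-1 came hphd-1 (12.2-fold lower, 3 probes), the nuclear receptor gene nhr-68 (6.36-fold), hach-1 (3.82-fold) and ech-6 (3.46-fold), while alh-8 (-0.43, 19 probes) and nhr-10 (-0.10) differed least. The sign of nhr-10 changed with the span trend removed (0.0016), after loess (0.033) and with a percentile over detected probes (0.041). Methionine cycle and vitamin B12 dependent genes were also lower, with 6 of 17 at least 2-fold lower, 0 at least 2-fold higher and a median of -0.58 at percentile 0.83. The nuclear receptor gene nhr-114 was 7.94-fold lower, the methionine synthase gene metr-1 4.06-fold, mtrr-1 3.43-fold, ahcy-1 3.05-fold (17 probes), mthf-1 2.74-fold and mmaa-1 2.02-fold. Of these mtrr-1 gave -0.68 with its brightest probe, and mmaa-1 was short of 2-fold in 3 other settings. The highest members were pccb-1 (0.27) and sams-5 (0.09, with probes that disagreed by an SD of 2.53 and 1.88 from the brightest).

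**Figure D2:**
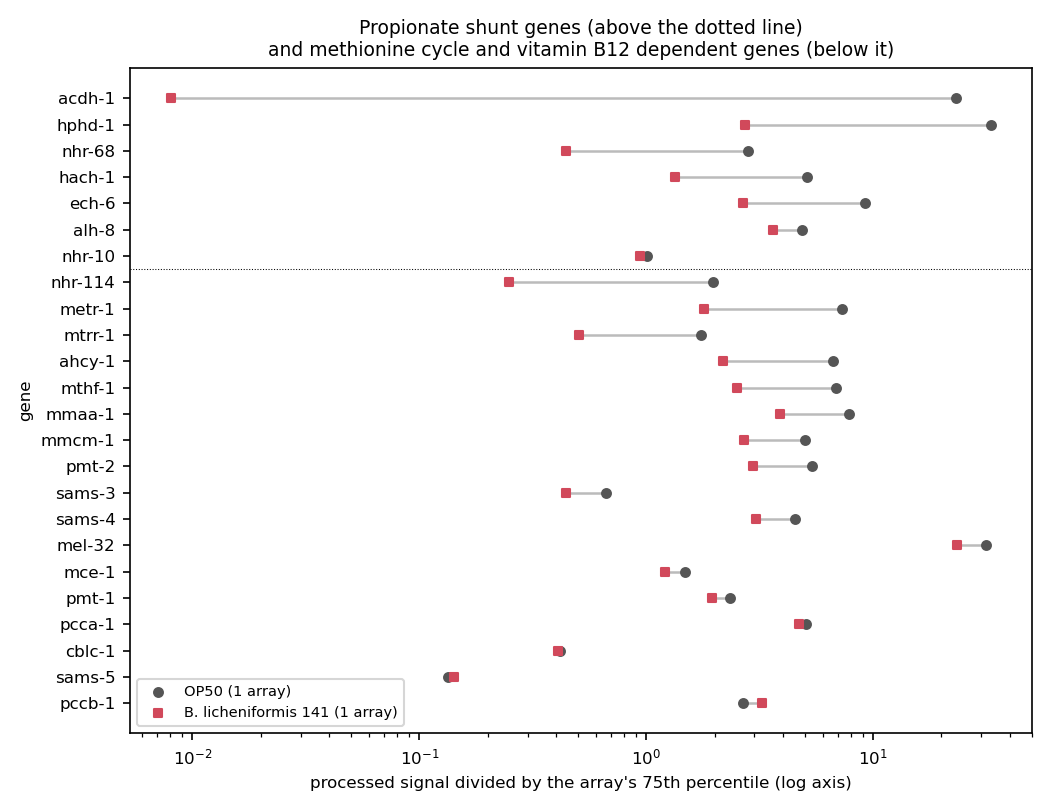
Processed signal divided by the array's 75th percentile (log axis) of 7 propionate shunt genes above the dotted line and 17 methionine cycle and vitamin B12 dependent genes below it, with OP50 as grey circles and B. licheniformis 141 as red squares, 1 array each. In this main setting all 7 shunt genes lie lower on B. licheniformis 141, by 2876-fold for acdh-1 and 12.2-fold for hphd-1. The small difference of nhr-10 changed sign in some other settings.

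Fat breakdown and fasting genes were higher with a wide spread. Their median was 1.02 at percentile 100, with 25 of 50 genes at least 2-fold higher and 7 lower. The enoyl-CoA hydratase family gene ech-9 (55.4-fold) and the lipase gene lipl-1 (32.1-fold) were highest, and acdh-1 and the fasting-induced acs-2 (8.24-fold lower) lowest. The difference of acs-2 was -3.04 in the main setting, -2.06 under normexp with faulty backgrounds replaced and -0.31 under planned normexp. Genes of fatty acid desaturation and elongation did not stand apart (percentile 25.2), with fat-7 and nhr-80 (1.09, below 2-fold in 5 other settings) at the upper end and acs-1 and the fatty acid synthase gene fasn-1 (-2.43) at the lower. Lysosomal and digestive protease genes were higher, with a median of 1.1 at percentile 100 and 11 of 21 genes at least 2-fold higher. The aspartyl protease genes asp-12 (12.7-fold) and asp-8 (5.09-fold) led, and cpr-5 (-1.67) and asp-13 (-1.31) were lowest. Peptide and nutrient transporter genes lay at percentile 10.3, with snf-9 (1.30, but 0.95 unscaled) and snf-2 (1.15, below 2-fold in 6 other settings) highest and the inositol transporter genes hmit-1.2 (13.6-fold lower) and hmit-1.1 (6.54-fold lower) lowest. Under planned normexp these transporter genes gave -0.51 and -0.03, and the list lay at percentile 0.51 when the mean replaced the median. Autophagy genes lay at percentile 84.0 (99.2 with the span trend removed), with epg-2 (3.83) and sqst-1 (1.97) highest and epg-4 (-0.70) and atg-5 (-0.36) lowest.

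Sperm genes were higher, and oocyte and germline genes lower. All 27 measured major sperm protein genes had positive differences under the main scaling, 18 of them at least 2-fold, with a median of 1.09 at percentile 100. They ranged from msp-81 (0.73) and msp-56 (0.83) to msp-31 (1.33, or 0.91 with the span trend removed) and msp-152 (1.78). These genes are near-identical copies whose probes can share targets, so they count as little more than 1 measurement, and their median was 0.67 with the span trend removed. Of 59 other sperm genes 33 were at least 2-fold higher and 2 lower (median 1.1, percentile 100), from ssq-4 (2.24) and nspd-5 (2.1) to spe-41 (-1.17) and spe-44 (-1.23), which gave 0.02 and -0.92 under planned normexp. Oocyte and eggshell genes had a median of -0.73 at percentile 0.0, with 7 of 20 at least 2-fold lower and 0 higher. Among them perm-4 (-1.36) and mex-5 (-1.33) were lowest and pos-1 (0.05) and cpg-1 (0.03) highest. Germline genes had a median of -1.05 at percentile 0.0, with 13 of 24 at least 2-fold lower, led by the germline Notch receptor gene glp-1 (-1.83) and the cohesin gene rec-8 (-1.73). Their highest members were nos-3 (0.28, probes disagreeing by an SD of 1.28, with -1.52 from the brightest) and him-3 (0.16). The mutated gene fem-1, which directs male and sperm fate, was 1.76-fold lower with 2 probes.

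Cuticle collagen genes were higher, with a median of 0.68 at percentile 100 and 57 of 131 genes at least 2-fold higher against 8 lower. That median was 0.33 unscaled and 1.56 under planned normexp. They were led by col-147 (77.6-fold) and dpy-14 (46.3-fold), and col-158 (-2.40) and col-68 (-2.29) were lowest. A further 32 collagen genes were above background on the B. licheniformis 141 array only and 1 on OP50 only. Larval moulting genes did not stand apart (percentile 72.6), with ptr-4 (2.35) and nas-36 (2.19) highest and nhr-23 (-2.09) and qua-1 (-1.63) lowest, although these turned to 0.12 and 1.71 under planned normexp. Body wall muscle genes lay at percentile 58.6, pharynx genes at 51.4 and neuron genes at 47.9. In these lists the highest members included pat-10 (0.65), act-4 (0.51), phat-4 (2.79), phat-2 (1.73), unc-119 (1.07) and unc-47 (1.01), the last pair below 2-fold in 5 and 6 other settings. The lowest were unc-22 (-2.15) and unc-54 (-1.86) of muscle, myo-5 (-1.39) and myo-1 (-0.74) of pharynx, and eat-4 (-0.99) and unc-13 (-0.90) of neurons. All of these but unc-54 changed sign under planned normexp, where unc-22 gave 0.58, myo-5 1.33, myo-1 0.35, eat-4 2.69 and unc-13 1.48. Without background correction eat-4 gave 0.04. Intestine genes lay at percentile 93.8 with a median of 0.28, from pgp-3 (1.52, or 0.97 under planned normexp) and ifb-2 (1.46) to erm-1 (-1.26, or -0.90 with the span trend removed) and mtl-2 (-0.82). The 5 vitellogenin genes lay at percentile 93.7, with vit-5 (0.77) and vit-4 (0.67) highest and vit-1 (-1.32) and vit-6 (-0.18) lowest.

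F-box genes had the highest median of all lists in the main setting, 1.28 at percentile 100, with 152 of 282 genes at least 2-fold higher and 6 lower. They ranged from fbxb-37 (47.5-fold higher) and fbxb-77 (32.6-fold higher) to fbxc-46 (-2.44, or -0.55 under planned normexp) and fbxa-72 (-4.31). Under planned normexp chemoreceptor genes had a higher median, 2.45 against 2.16. Histone genes, many of them near-identical copies, had a median of 0.69 at percentile 100 (0.26 with the span trend removed), with his-24 (24.9-fold) and the linker histone gene hil-3 (16.3-fold) highest and his-11 (-1.56, or -0.72 under planned normexp) and his-58 (-0.54) lowest. The other large families did not stand apart from random lists matched on signal, although against unmatched lists nuclear hormone receptor genes lay at percentile 99.99 and chemoreceptor genes at 99.82. Nuclear hormone receptor genes lay at percentile 89.5 with nhr-99 (2.85) and nhr-129 (2.52) highest and nhr-68 and nhr-114 lowest. Chemoreceptor genes lay at percentile 83.0, where 130 of 1399 on the array were measured, with str-148 (3.75) and str-154 (3.31) highest and srh-237 and sra-14 (-2.65, or -0.37 under planned normexp) lowest. Neuropeptide genes lay at percentile 90.8, from nlp-39 (79.0-fold higher) and nlp-25 (2.24) to nlp-16 (-0.98, or 0.42 under planned normexp) and nlp-59 (-2.69).

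Stress and housekeeping lists stayed within the random range in the main setting. Heat shock protein genes lay at percentile 53.8, with hsp-16.21 (2.97) and hsp-12.6 (2.75) highest and hsp-110 (-1.64) and hsp-2 (-1.63) lowest. Mitochondrial unfolded protein response genes lay at percentile 66.2, with ubl-5 (1.003, below 2-fold in 4 other settings) and dve-1 (0.81, or 1.90 under planned normexp) highest and hsp-60 (-1.43, 10 probes) and atfs-1 (-0.96) lowest. Endoplasmic reticulum stress genes lay at percentile 4.45 (2.01 without background correction, 2.24 with the brightest probe and 1.62 under normexp with faulty backgrounds replaced), with crt-1 (0.76) and pdi-2 (0.62) highest and atf-4 (-1.37) and xbp-1 (-1.01, short of 2-fold in 4 other settings) lowest. Respiratory chain genes lay at percentile 27.6, from cyc-2.2 (1.24, below 2-fold in 3 other settings) and cox-17 (0.61) to ucr-1 (-0.87, but 1.67 under planned normexp and 0.17 with its brightest probe) and ucr-11 (-0.99). Ribosomal protein genes lay at percentile 93.6, and 1 of 77 passed 2-fold, rpl-24 (-1.58), whose 4 probes disagreed by an SD of 1.35 and which turned to 0.44 with its brightest probe and 1.46 under planned normexp. The highest were rpl-41.1 (0.98) and rpl-42 (0.96, or 2.55 under planned normexp), and rps-10 gave -0.58. In all, 16 of the 43 lists stood above and 5 below the middle 95% of random lists. By chance 2.15 would do so if the genes within a list varied independently. Genes of a family or tissue can move together, so 2.15 is no measure of chance here. The 21 lists share genes, and their percentiles describe these 2 arrays.

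**Figure D3:**
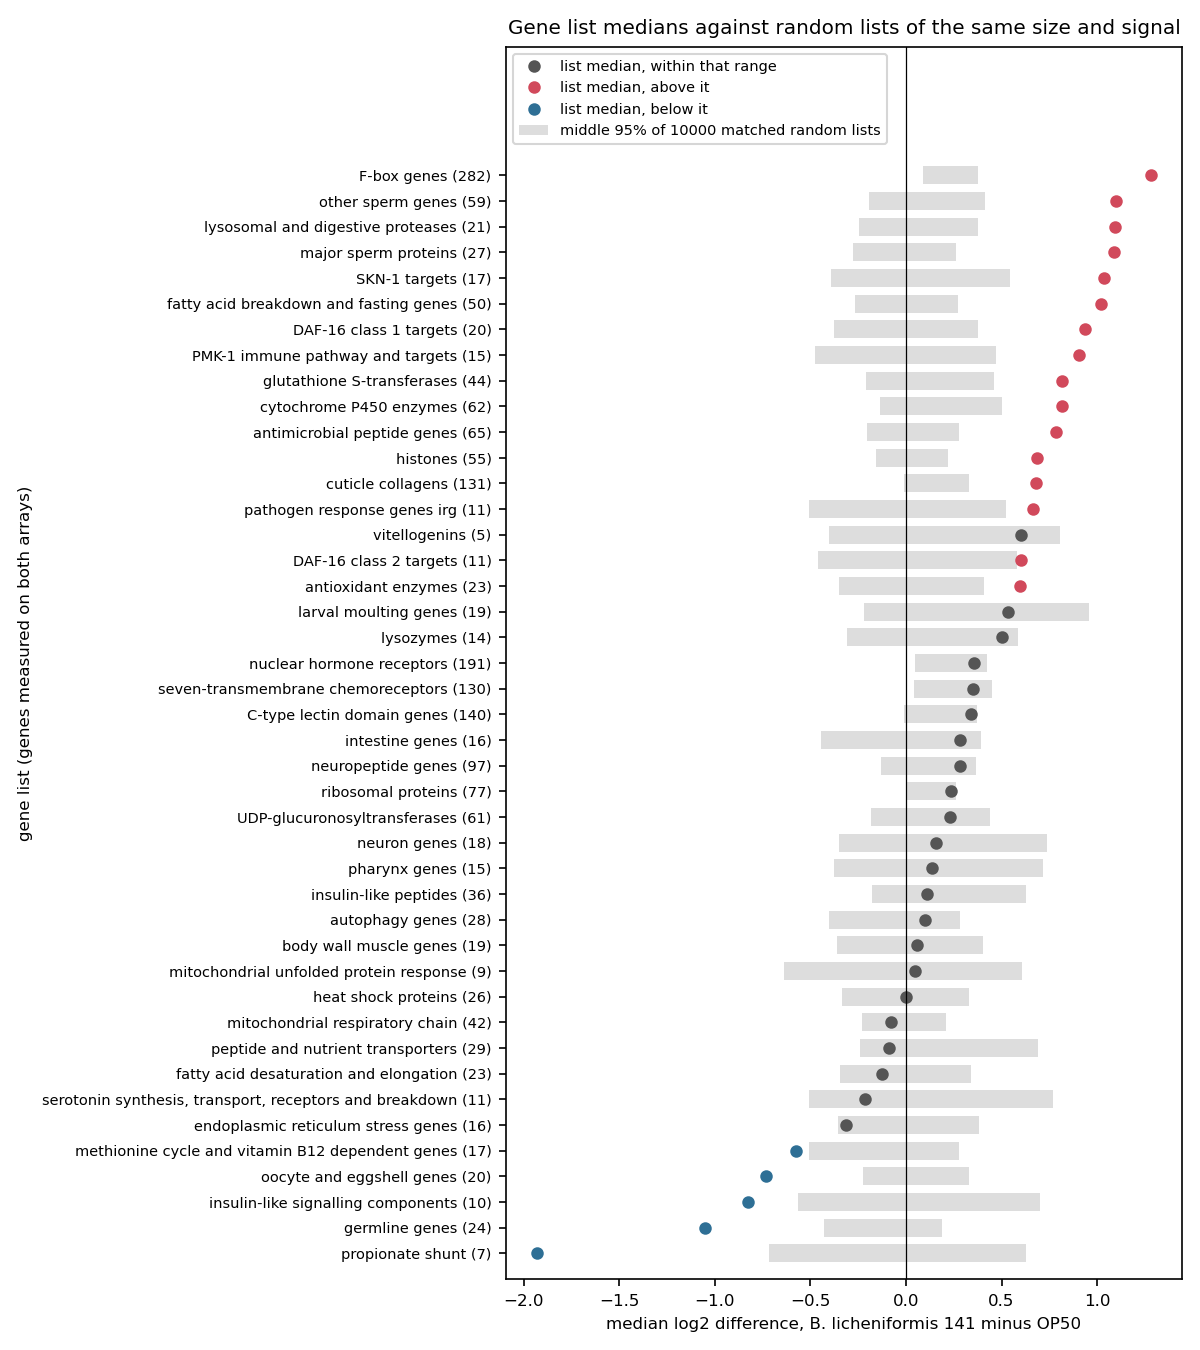
Median log2 difference, B. licheniformis 141 minus OP50, of 43 gene lists (dots) against the middle 95% of 10000 random lists matched on size and signal (grey bars). The medians run from -1.93 for the propionate shunt to 1.28 for F-box genes, with 16 lists above and 5 below their bars.

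Gene span moved with the difference between the arrays. Across 14956 genes with an annotated span the rank correlation of span and difference was -0.26, where genes are not independent replicates. The 10% of genes with the shortest spans (median 544 bp) had a median difference of 0.44, and the 10% with the longest spans (median 10808 bp) -0.40. Many collagen, sperm protein and histone genes are short, so every list was also set against random lists matched on signal and span. All 21 lists kept their side outside the middle 95%, although this decides little for near-identical copies such as the major sperm protein genes, with insulin-like signalling at percentile 1.49, methionine cycle genes at 1.37, antioxidant enzymes at 98.8 and DAF-16 class 2 targets at 98.9. Vitellogenin genes (99.2) and intestine genes (99.0) then stood above it as well. With the span trend removed in place of matching, antioxidant enzymes lay at percentile 92.2 and no longer stood apart.

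**Figure D4:**
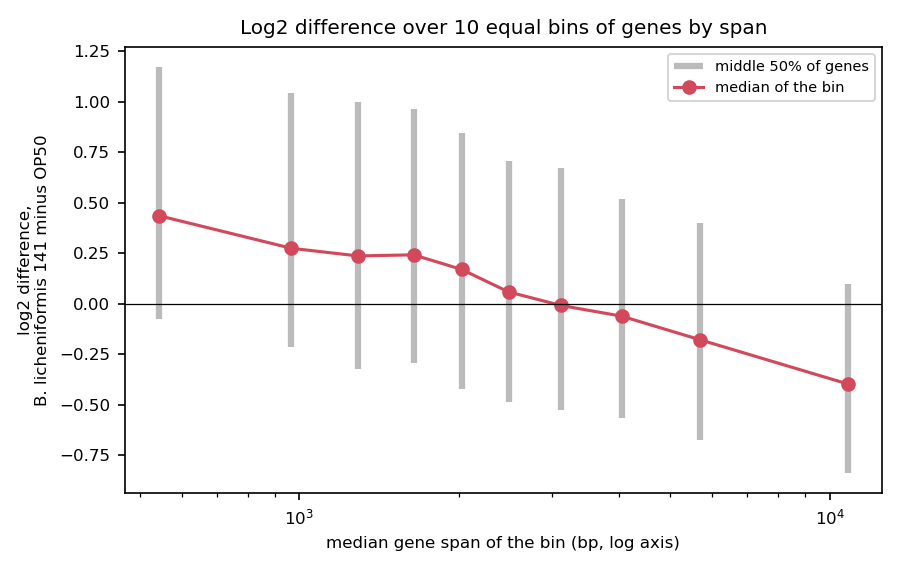
Log2 difference, B. licheniformis 141 minus OP50, over 10 equal bins of genes by span (bp, log axis), with the median of each bin as red dots and the middle 50% of its genes as grey bars. The medians fall from 0.44 in the bin of shortest spans to -0.40 in that of the longest.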

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

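Probes without a gene name were not part of the comparisons, and they showed signals that differed between the diets. Of 4373 such probes well above background on both arrays, 375 were at least 2-fold higher (8.58%) and 768 at least 2-fold lower (17.6%) on B. licheniformis 141. Named probes were tilted the other way, with 17.1% higher and 10.8% lower. These shares are for the main scaling only. The tilt of named genes depended on it, since 47.7% of changed genes were higher with median centring and 39.4% unscaled. The highest unnamed probe, A_12_P114408 for transcript cluster TC206377, differed by 6.78, from 98.0 to 8447 units. The lowest, A_12_P113053 for NP012779, differed by -6.75, from 9213 to 67.1 units. No explanation was tested for either.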

How the results depend on the processing

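With 1 array per diet no replicate could be left out. No paired analysis was possible because each diet has a single array. Genes at least 2-fold higher numbered 2894 and lower 1412. Alternatives that moved either count by over 1.5 times were 1.5-fold (4564 and 3221) and 3-fold thresholds (1436 and 390), planned normexp (6728 and 745), no scaling (1877 and 2893, chosen after seeing the data), median centring (2379 lower), no filter on dim probes (4492 higher) and the stricter filter (1582 higher). Thresholds and filters act by construction. Scaling moved the median of all genes from 0.07 to between -0.29 and 0.21, planned normexp to 0.72. Planned normexp met 3 spots of the B. licheniformis 141 array whose background exceeded their signal by more than a cutoff. With these backgrounds replaced (the cutoff and the replacement were chosen after seeing the data) normexp gave a median of 0.10, 2243 higher and 1007 lower. Of 145 named genes changed at least 2-fold, 10 reversed in some setting. Under planned normexp these were cyp-31A1 (0.0076), nhr-23 (0.12), rpl-24 (1.46), myo-5 (1.33), spe-41 (0.024), gsto-3 (0.50), gst-9 (0.048), qua-1 (1.71) and unc-22 (0.58). Without the filter cat-4 gave -0.55, and rpl-24 gave 0.44 with the stricter filter and with the brightest probe, which leave out probes that disagree. With the 3 faulty backgrounds replaced all 9 genes reversed by planned normexp were negative again (-1.56 to -0.52), which ties those reversals to the 3 spots. Of 215 genes followed, whatever their size, 28 changed sign under planned normexp and 0 with the backgrounds replaced. The 2-fold call was lost for 29 of 145 named genes under planned normexp and for 9 or fewer in each other setting (92 of the genes were measured under the stricter filter). Of 21 lists that stood apart, 18 did so under all 17 alternatives, and all 21 medians kept their sign in the 14 settings that recompute them. The exceptions were DAF-16 class 2 targets, antioxidant enzymes (92.2 with the span trend removed) and the irg list (94.5 with unmatched random lists), and 28 of 731 list percentiles changed call. Of the 22 lists that did not stand apart 11 did so in some setting: C-type lectins (2.15 to 99.85), chemoreceptors (99.82) and nuclear hormone receptors (99.99) with unmatched lists, endoplasmic reticulum stress (1.62 to 2.24), serotonin (0.97 without the filter), transporters (0.51 with means), lysozymes (98.4 without the filter, 98.5 with the stricter one), vitellogenins (99.2) and intestine genes (99.0) with span matching, and insulin-like peptides (0.1) and autophagy genes (99.2) with the span trend removed. Dim genes limit the depth, since 3290 genes were above background on neither array.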

Other observations

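The tests of development and of signal above its lowest 10% were chosen after their results were seen. Some of the lowest genes came in pairs of consecutive sequence names. F18E3.12 was 260-fold and F18E3.11 28.3-fold lower, and T05E12.6 was 82.3-fold and srh-237 (T05E12.7) 65.7-fold lower. The genes acdh-1 and acdh-2 had the lowest difference and 1 of the strongest lower bounds (at least 43.8-fold), although the fat breakdown list that holds the acyl-CoA dehydrogenase genes stood apart as higher.

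Propionate shunt genes were lower on B. licheniformis 141, with acdh-1 at -11.49. The span trend between the arrays is argued against as the cause, since among lists matched on signal and span the median lay at percentile 0.0. A difference that depends on signal is argued against as well, since the percentile was 0.0 after loess. As a hypothesis, B. licheniformis 141 may have supplied more vitamin B12 than OP50, which would lower shunt and methionine cycle genes together, and the methionine cycle list lay at percentile 1.37 of lists matched on signal and span. Bacterial vitamin B12 and propionate were not measured here, and other nutrients and the confounded slide and scan stay open.

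Sperm genes were higher while oocyte and germline genes were lower. Of lists matched on signal and span, other sperm genes lay at percentile 100, oocyte and eggshell genes at 0.01 and germline genes at 0.0. These lists hold gene families or genes of 1 tissue that can move together, so the percentiles are no measure of chance. Their medians argue against the span trend as the only cause. In all other settings, span trend removal included, other sperm genes stayed at 0.75 or above. Oocyte and eggshell genes stayed at -0.59 or below and germline genes at -0.91 or below. The span trend cannot be told apart for the major sperm protein genes, whose percentile of 99.99 decides nothing because near-identical copies were ranked against lists of separate genes. Younger or more slowly developing worms on the B. licheniformis 141 lawn cannot be told apart from other causes, since the larval moulting list lay at percentile 97.2 with span matching and 72.6 without. Cuticle collagen genes were higher as well, with 57 of 131 at least 2-fold higher and 8 lower. They could go with slower development, but their bearing on it was not tested. Of the 5 vitellogenin genes 3 were higher (median 0.60, percentile 93.7, or 99.2 with span matching). Their bearing on development was not tested either. A smaller share of germline RNA, with its mix of sperm and other RNA unchanged, is argued against as the cause of the whole pattern. It would lower sperm genes too, which are expressed in the germline, but 50 of 59 other sperm genes were higher. This count cannot decide about a smaller germline whose mix also differed. For the lower oocyte and germline genes alone a smaller share of germline RNA stays open and untested. An effect of the food on the germline, untested, and the confounded slide and scan also stay open. So does a difference in temperature between the cultures, since fem-1(hc17) and fer-15(b26) are temperature-sensitive and no culture temperature is stated.

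Genes with a long span were lower and genes with a short span higher on B. licheniformis 141. The families of the 43 lists are argued against as the only cause, since without every gene of these lists the rank correlation was still -0.25 over 13027 genes. Families outside the lists were not removed, so the test cannot decide about them. A signal-dependent difference is argued against above the lowest 10% of mean signal, where the weakest correlation was -0.21, and cannot be told apart within that 10%, where it was -0.037. Within 171 muscle, pharynx, neuron, ribosomal protein and respiratory chain genes the correlation was -0.32 (bootstrap 95% interval over genes -0.46 to -0.16). A difference in RNA quality, labelling or slide that acts on all long transcripts would give such a value, so it stays possible. The value cannot single it out, since an effect of the food could give the same. The 171 genes also pool classes that may differ in both span and response. Gene span stood in for transcript length, which was not available. An effect of the food on long transcripts stays open and untested.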
